A study of Homo sapiens with 6 samples.

How the data were processed

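RNA from cells labelled Huh-7 was sequenced in 6 samples, 3 transfected with miR-27a-3p mimics and 3 with a negative control. Per the labels' protocols, transfection used a lipid reagent, cells were taken 48 h after it by trypsin digestion, RNA was extracted with Trizol, and libraries were made from 1 µg of total RNA with a dual-mode mRNA kit. Groups were taken from the treatment label of each sample. The labels do not say whether the 3 samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

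The deposited tables give 1 FPKM value per gene and sample for 58174 genes with Ensembl identifiers and positions, per the file headers. FastQC, HISAT2 and the hg38 build are named by the submitters' processing notes; their versions, the tool that turned alignments into FPKM, its strand setting and the annotation release are not given in the sources used here. The 6 tables of single samples were checked against the table of the whole series and held identical values. FPKM are fragments scaled to gene length and to the library's total, so they are relative and a gene can appear lower because others take a larger share. To look for the depth, FPKM was multiplied by gene length from GENCODE 29. In each sample 584 to 645 genes lay within 1% of 1 shared value and 202 to 292 within 1% of its double, and that value was taken as 1 fragment, which gives the implied fragment numbers in the results. Only 11.5% to 17.0% of the low values were whole multiples of it at that tolerance, so reads per gene were not recovered, no count test was run, and no counting interval or detection limit is given. This check was made after the other results had been seen. A value of 0 means only that the gene is listed at 0.

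Current gene symbols were assigned through identifiers, of which 57392 matched the symbol table and 57836 matched GENCODE 29, which also gave the biotypes. Genes with a mean of at least 1 FPKM over the 6 samples were tested, 14439 in all. Differences between groups were tested with limma-trend (limma 3.58.1 in R 4.3.3) with robust empirical Bayes moderation on log2(FPKM + 0.5), with no further scaling and no covariates, and Benjamini-Hochberg adjustment at 0.05. Log2 fold changes are mimic against negative control on that scale, which understates the change of genes with low values. Choices of test, gene lists and named genes were fixed before the data were examined, with a count-based test as the first choice for counts and this test for normalized values. The files hold normalized values, so the count-based test was not used.

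The genes named in the text follow a fixed rule. They are the 8 protein-coding genes with the largest rise and the 8 with the largest fall among those called with a mean of at least 5 FPKM and with groups that do not overlap; up to 3 called members with the smallest p of each gene list that had at least 3 called members or was called itself; up to 2 members with the smallest p of other lists; the 6 called genes that fell, held an 8mer seed match and had the smallest p; and the genes MIR23AHG and MIR24-2 of the miR-23a cluster. Genes outside the rule are named as chosen after their values were seen. A gene that the rule takes is not reported here.

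There were 38 gene lists, covering reported miR-27 targets, drug handling, DNA repair, cell death, cell cycle, metabolism, liver functions, stress and immune responses, RNA quality and other cell types. The 36 lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, adjusted over those lists. Camera with an estimated correlation and fry were run as alternatives.

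Seed matches of miR-27a-3p, complementary to its nucleotides 2 to 8, were searched in the longest annotated 3' UTR of each gene in GENCODE 29. The classes were 8mer (ACTGTGAA), 7mer-m8 (ACTGTGA) and 7mer-A1 (CTGTGAA). Genes with no annotated 3' UTR were left out as not searched. Each class was compared with genes without a match by the difference of medians and by camera, adjusted over the 4 comparisons. For each of the 16384 possible 7mers, the log2 fold change was regressed across genes on the presence of the word with log2 UTR length and GC content as covariates, and the words were ranked by Wald z from the most negative. Genes are not independent replicates, so this rank carries no p-value.

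The limma step was tested on simulated values for the 14439 genes with the real means and spreads and 200 changed genes. It recovered 7.5% of genes changed 1.5-fold, 43.3% of those changed 2-fold and 92.4% of those changed 4-fold, with 4 false calls. With so few changed genes the Benjamini-Hochberg cut is stricter than in the real data, where 7453 genes were called. These rates therefore do not describe the real fit. In the test of the word ranking, a seeded fall of 0.1 on the log2 scale placed the seed word at rank 1 over 11465 genes, and no seeded fall placed it at rank 1957. Fold changes were randomly reordered among genes a single time for each seeded fall, so rank 1957 is a single draw and not a typical rank. A seeded list shift of 0.5 gave a camera p of 1.65e-22, and 1 of 100 random lists passed 0.05. Simulated genes varied independently, so this does not check camera for lists of correlated genes.

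The alternatives fixed beforehand were the replicate number as a block, quantile normalization, median-of-ratios scaling, no filter on low values, a minimum mean of 5 FPKM, pseudocounts of 0.1 and 1, a block with GC and length correction, leaving out each sample, other set tests, another UTR choice and no UTR covariates. After seeing the data 4 were added: scaling to the total without mitochondrial genes, GC and length correction without the block, protein-coding genes only, and leaving out replicate 3 of both groups. Of the 14439 genes, 14402 had a length and GC content. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.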

Results

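The series asks how miR-27a-3p bears on the cisplatin sensitivity of hepatocellular carcinoma. Transcriptomes of cells labelled Huh-7, an established line from a human hepatocellular carcinoma, were compared between 3 samples transfected with miR-27a-3p mimics, which are synthetic double-stranded RNAs that imitate the mature microRNA, and 3 samples transfected with a negative control. The labels name no cisplatin treatment. RNA was taken 48 h after transfection, and expression is given as FPKM. Read numbers are not given, but FPKM times gene length piled up at 1 value in each sample and at its double, as whole fragments would. Taken as 1 fragment, that value implies about 19300000, 21100000 and 17000000 fragments in control samples 1, 2 and 3, and 31000000, 25100000 and 28200000 in mimic samples 1, 2 and 3. Values below are group means ± SD of 3 samples, log2 fold changes are mimic against negative control with their standard error (SE), and adjusted p-values are from limma.

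The samples separated by group. Pearson correlations of log2 FPKM across genes were 0.971 to 0.982 within groups and 0.881 to 0.915 between them, and the first principal component held 75.6% of the variance and parted the groups. Genes are not independent replicates, so these correlations describe the samples only. Mimic samples had fewer genes at 1 FPKM or more, with 13218, 13250 and 13007 against 15494, 15109 and 15191 in the controls. Most of that gap lay outside protein-coding genes, of which mimic samples held 11156, 11202 and 11068 and controls 11791, 11726 and 11682. Genes of other biotypes numbered 2033, 2019 and 1908 in mimic samples and 3659, 3339 and 3459 in controls. The share of summed FPKM from mitochondrial genes was 16.9%, 18.4% and 32.8% in control samples 1, 2 and 3, and 14.6%, 24.3% and 38.9% in mimic samples 1, 2 and 3, so sample 3 was the highest in both groups.

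**Figure D1:**
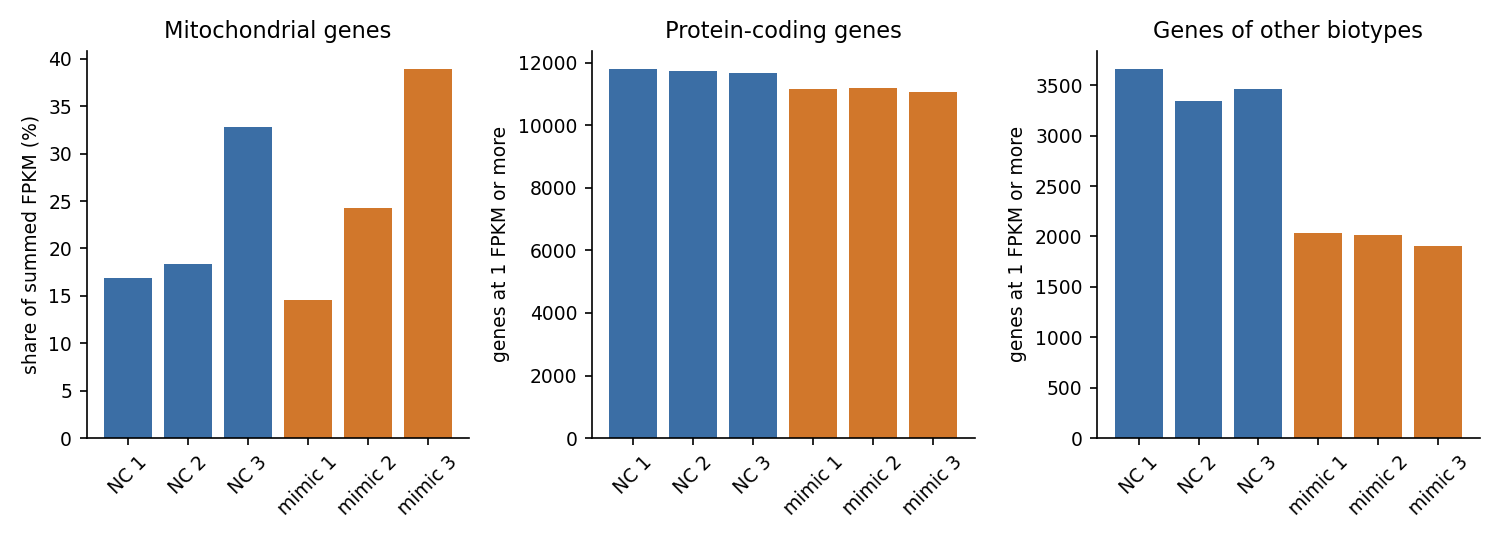
Bars give, for each of the 6 samples (blue, negative control, NC; orange, mimic), the share of summed FPKM from mitochondrial genes in percent and the number of protein-coding genes and of genes of other biotypes at 1 FPKM or more. Genes of other biotypes number 1908 to 2033 in mimic samples and 3339 to 3659 in controls, while the mitochondrial share overlaps between groups.

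Of 14439 genes tested, 1735 rose and 5718 fell in mimic samples. Of these, 356 rose and 2666 fell at least 2-fold. The groups did not overlap in 60.5% of genes, against 10% by chance. The median log2 fold change of all tested genes was -0.29, and the balance of calls followed this shift. Higher genes made up 23.3% of the calls on the deposited scale, 49.6% after median-of-ratios scaling (3889 higher, 3953 lower) and 52.2% after quantile normalization (3592 higher, 3289 lower). Changes smaller than the shift therefore have a direction only relative to a chosen scale, and counts per gene list are given on the deposited scale and after median-of-ratios scaling, where the median was 0.01. The group difference in fragment number runs against the gene counts, since the mimic samples with fewer genes at 1 FPKM have the larger implied number of fragments.

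The 8 largest falls among protein-coding genes included those of immediate early transcription factors. FOSB on chromosome 19 (45467995 to 45475179, hg38) went from 87.5 ± 11.6 to 0.452 ± 0.0755 FPKM (log2 fold change -6.52, SE 0.15, adjusted p = 5.51e-07). EGR1, another transcription factor induced within minutes of stimulation, went from 60.5 ± 10.7 to 0.259 ± 0.0886 (-6.32, SE 0.17, adjusted p = 1.31e-06), and FOS from 490.0 ± 51.2 to 9.53 ± 2.58 (-5.64, SE 0.21). CCN2, which encodes a matricellular growth factor, fell by 5.02 on the log2 scale, NFKBIZ, an IkappaB family regulator, by 5.00, and the stress-responsive ATF3 by 4.76. The reductase gene DHRS2 fell by 4.56 and the orphan nuclear receptor gene NR4A1 by 4.37.

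The largest rises were in ENSG00000257341, an unnamed protein-coding gene on chromosome 14 (4.01, SE 0.40), and in UGT1A7, a glucuronosyltransferase gene, from 1.17 ± 0.599 to 25.1 ± 5.00 FPKM (3.99, SE 0.30, adjusted p = 6.34e-05). AKR1C2, an aldo-keto reductase gene, rose from 12.3 ± 1.62 to 151.8 ± 41.6 (3.54, SE 0.21), SLC39A1, a zinc transporter gene, by 2.95 on the log2 scale (SE 0.38), and ACTN4, which encodes an actin crosslinker, from 51.6 ± 8.16 to 257.0 ± 24.6 (2.31, SE 0.16). MT-ND6 (3.64, SE 0.69) and MT-ATP8 (3.36, SE 0.79) also ranked here, with large SDs. Both climbed with the sample number in both groups. MT-ATP8 was at 505.4, 1519 and 3350 FPKM in control samples 1, 2 and 3 and at 6497, 13790 and 31040 in mimic samples. By limma with the replicate number as a block, adjusted p was 0.000185 for MT-ND6 and 0.000315 for MT-ATP8, against 0.00442 and 0.01065 without it. UGT1A7 shares exons with its locus neighbours, AKR1C2 has near-identical paralogs and MT-ATP8 overlaps MT-ATP6. MT-ND6 lies next to MT-ND5 on the other strand, and the strand setting is not given. The assignment of reads to UGT1A7, AKR1C2, MT-ATP8 and MT-ND6 is therefore uncertain. ENSG00000268173 on chromosome 19 completed the 8 (3.24, SE 0.90, adjusted p = 0.0246). It was at 1.62, 0.2515 and 0.1174 FPKM in control samples 1, 2 and 3. Mimic sample 1, at 2.025, lay close to control sample 1, while mimic samples 2 and 3 were at 15.89 and 19.49. Its adjusted p was 0.0917 without control sample 2, 0.085 without control sample 3 and 0.0668 without mimic sample 3.

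**Figure D2:**
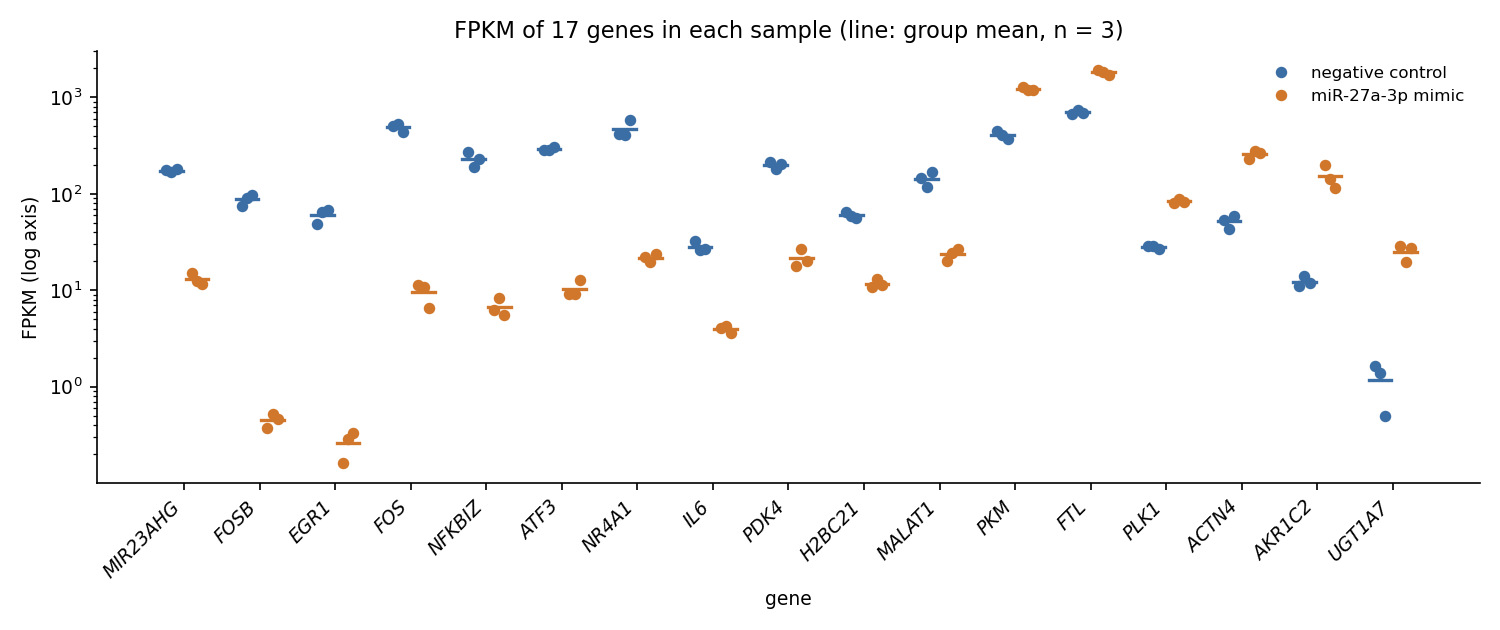
Points are FPKM of single samples on a log axis for 17 genes, with negative control in blue and mimic in orange, and lines mark the mean of 3 samples. Groups do not overlap in any gene shown, with FOSB at 74.5 to 97.0 FPKM in controls and 0.370 to 0.519 in mimic samples.

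Genes of the locus that encodes miR-27a itself fell in mimic samples. MIR23AHG, named for its role as host gene of the cluster and listed under an older clone name at chromosome 19 from 13834516 to 13836289 (hg38, minus strand), went from 173.9 ± 6.67 to 13.2 ± 1.85 FPKM (log2 fold change -3.68, SE 0.14, adjusted p = 4.73e-06). MIR24-2, from 13836287 to 13836359 and so almost wholly beyond that interval, was listed at 13.6, 16.5 and 12.7 in controls and 0.849, 0.249 and 0.000056 in mimic samples (adjusted p = 7.77e-05). The MIR27A hairpin, from 13836440 to 13836517, was chosen after its values were seen and was listed at 10.1, 11.2 and 8.94 in controls and 0, 0.398 and 0.473 in mimic samples. Such libraries do not measure the mature microRNA or the transfected mimic.

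Genes with a seed match of miR-27a-3p in the 3' UTR were compared with 8155 genes without one, to ask whether the mimic's direct targets were lower. The 751 genes with an 8mer, the longest match, had a median log2 fold change of -0.31, against -0.13 without a match, and were lower by camera (difference -0.18, adjusted p = 0.042 over the 4 comparisons). Genes with any match (3310) differed by -0.14 (adjusted p = 0.131), and by -0.03 after quantile normalization or after GC and length correction. Those with a 7mer-m8 differed by -0.14 (adjusted p = 0.131) and those with a 7mer-A1 by -0.12 (adjusted p = 0.214). The 8mer call was lost with an estimated correlation (adjusted p = 0.757), after GC and length correction (difference -0.08, adjusted p = 0.839), after quantile normalization (difference -0.07, adjusted p = 0.783) and with no filter on low values (adjusted p = 0.262). It was also lost with the replicate number as a block (adjusted p = 0.0564) and without control sample 3 (0.0664), mimic sample 1 (0.162) or sample 3 of both groups (0.066), and ranged from 0.0118 to 0.839 over 20 alternatives. Among 16384 words, the seed match ACTGTGA ranked 1686 from the most negative (coefficient -0.04, z = -2.29). In a test of the ranking on randomly reordered fold changes, a seeded fall of 0.1 gave rank 1 and no fall gave rank 1957. Each came from a single reordering, which also removes the real link between fold change and UTR words. The test therefore gives no reference for the real rank. On the deposited scale AATTTAT (z = -6.10), AAATATT (-5.98) and TATTTAT (-5.86) were lowest and CCCTCCC highest (4.67), while TATCGGG was lowest after quantile normalization (-4.58).

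**Figure D3:**
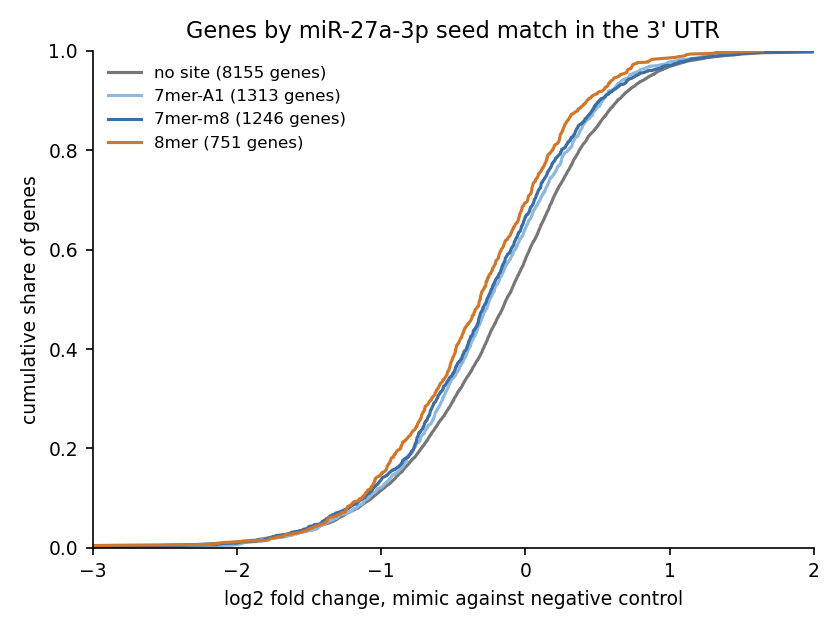
Cumulative share of genes (vertical axis) by log2 fold change of mimic against negative control (horizontal axis) for 8155 genes without a seed match and for genes whose best match is a 7mer-A1, 7mer-m8 or 8mer. The 8mer curve lies furthest left, with a median of -0.31 against -0.13 for genes without a match.

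The 8mer genes that fell with the smallest p were FOSB, TCIM, a regulator of Wnt signalling (-4.00, SE 0.16, from 8.19 ± 0.889 to 0.0428 ± 0.0435 FPKM), PDK4, a kinase that restrains pyruvate oxidation (-3.19, SE 0.17, from 200.3 ± 16.6 to 21.7 ± 4.66), NKTR (-2.79, SE 0.15), the kinase gene SIK1 (-2.09, SE 0.13) and NHS (-2.16, SE 0.17). Of 35 tested genes reported earlier as miR-27 targets, 13 were lower and 5 higher, or 6 lower and 8 higher after median-of-ratios scaling (camera adjusted p = 0.765). CYP1B1, a xenobiotic-metabolising cytochrome (-1.97, SE 0.16), and the signal transducer SMAD2 (-1.55, SE 0.15) fell. PINK1, which is also in this list and holds a 7mer-A1 match, was 1 of the 5 that rose (1.47, SE 0.19). Of 29 genes of the microRNA machinery, 11 were lower and none higher on the deposited scale, and 7 were lower and 6 higher after median-of-ratios scaling (adjusted p = 0.595). They included the deadenylase gene PAN2 (-1.67), TNRC6A (-1.07) and DICER1 (-1.09).

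Immediate early and stress genes fell as a group, with 21 of 29 tested members lower and 4 higher (19 and 5 after median-of-ratios scaling; 21 and 4 adjusted over the list alone). The list was called lower (camera adjusted p = 0.00304), but not with an estimated correlation (adjusted p = 0.898; range over 20 alternatives 1.01e-05 to 0.898). Its estimate was 0.013, near the preset 0.01, and no list had an adjusted p under 0.898 in that test. NF-kappaB and inflammatory genes had 11 of 22 members lower and 4 higher (10 and 7 after scaling; adjusted p = 0.376). Among them the chemokine gene CXCL8 fell by 3.97 on the log2 scale (SE 0.18, adjusted p = 8.24e-06) and the cytokine gene IL6 from 28.3 ± 3.33 to 3.97 ± 0.32 (-2.69, SE 0.14). Of 35 interferon-stimulated genes 16 were lower and 2 higher (15 and 9 after scaling). The camera adjusted p was 0.286, and 0.0361 after quantile normalization. Adjusted p ranged from 0.00966, given by fry without comparison to other genes, to 0.898. TRIM22 (-2.83), IFI44 (-1.71) and the antiviral sensor OAS2 (-1.42) were among the lower. The ATF4 and integrated stress response list was divided, with 8 of 32 higher and 7 lower (17 and 6 after scaling; adjusted p = 0.0689). Camera called it higher with the replicate number as a block (adjusted p = 0.0373), with no filter on low values (0.00494) and with mitochondrial genes left out of the total (0.043). It was also called without mimic sample 3 (0.0439) and without sample 3 of both groups (0.0433), but not with an estimated correlation (0.898), and the direction by fry was lower (0.252). PPP1R15A, a stress-induced phosphatase subunit, fell (-2.20, SE 0.12), and DDIT4, an inhibitor of mTORC1, rose from 86.9 ± 12.4 to 255.2 ± 72.0 FPKM (1.52, SE 0.22). In the unfolded protein response list 3 of 26 were higher and 7 lower (12 and 3 after scaling; adjusted p = 0.203). The chaperone genes CANX (2.02, SE 0.18) and HYOU1 (1.12, SE 0.16) rose, and the sensor gene ERN1 fell (-1.25, SE 0.13).

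Replication-dependent histone genes, whose mRNAs end without a poly(A) tail, fell in 26 of 30 tested members, with none higher (23 lower and 1 higher after median-of-ratios scaling; 26 and 0 adjusted over the list alone). The list was called lower (camera adjusted p = 3.99e-05), but not with an estimated correlation (adjusted p = 0.898; range 4.04e-07 to 0.898). H2BC21 went from 59.8 ± 3.87 to 11.7 ± 1.28 FPKM (-2.30, SE 0.13), with H2BC7 (-2.86, SE 0.20) and H2AC11 (-1.57, SE 0.12). Histone genes are near-identical copies, so their single values are uncertain. Nuclear and non-polyadenylated RNAs were lower in 5 of 9 members and higher in none on both scales (adjusted p = 0.188). After quantile normalization camera called them lower (adjusted p = 0.0361), as it did at a mean of at least 5 FPKM (0.0319) and with the block and GC and length correction (0.0411). With an estimated correlation it did not (0.898, the upper end of a range from 0.0319). The nuclear RNA MALAT1 went from 143.4 ± 25.1 to 23.6 ± 3.23 FPKM (-2.57, SE 0.17), NEAT1, the scaffold of paraspeckles, from 287.2 ± 50.8 to 72.5 ± 16.3 (-1.99, SE 0.21), and GAS5 from 314.5 ± 23.7 to 162.7 ± 47.2 (-0.98, SE 0.21).

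By biotype, 3778 of 11571 protein-coding genes were lower and 1624 higher, with a median log2 fold change of -0.17. That balance turned on other scales, with 2358 lower and 3678 higher after median-of-ratios scaling and 2605 and 2857 after GC and length correction. Among 545 lincRNA genes 396 were lower and 10 higher (median -0.97), and among 789 antisense genes 564 were lower and 27 higher (median -0.91). Of 119 snoRNA genes 87 were lower and 1 higher (median -1.29), and of 32 snRNA genes 25 were lower and none higher (median -1.53). After median-of-ratios scaling the medians were 0.13 for protein-coding, -0.73 for lincRNA, -0.65 for antisense, -1.06 for snoRNA and -1.31 for snRNA genes. After GC and length correction they were 0.05, -0.54, -0.52, -0.19 and -0.36 in that order, so most of the difference of the snoRNA and snRNA classes was lost. That correction left 34 snoRNA genes lower and 8 higher, and 10 snRNA genes lower and 1 higher. Antisense and overlapping genes share reads with their partners where counting ignores strand, and the strand setting is not given in the sources used here.

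Targets of NFE2L2, the transcription factor of the antioxidant response, rose in 15 of 30 tested members and fell in 4 (21 and 3 after median-of-ratios scaling; 15 and 4 adjusted over the list alone). The list was called higher (camera adjusted p = 0.000117), but not with an estimated correlation (adjusted p = 0.898) or by fry (0.0682; range 8.68e-07 to 0.898). FTL, the light chain of the iron store ferritin, went from 703.3 ± 33.9 to 1816 ± 97.8 FPKM (1.37, SE 0.16, adjusted p = 0.000316), and AKR1C2 rose as above, while ABCC3, an efflux transporter gene, fell from 121.9 ± 5.95 to 44.4 ± 2.98 (-1.45, SE 0.13). Glycolysis and hypoxia genes were higher in 14 of 35 and lower in 5 (21 and 4 after scaling; 14 and 5 adjusted over the list alone; camera adjusted p = 0.000117, and adjusted p = 0.898 with an estimated correlation and 0.105 by fry; range 3.92e-06 to 0.898). The glycolytic enzyme genes PKM (1.58, SE 0.16, from 407.0 ± 39.2 to 1218 ± 45.6 FPKM), GPI (1.28, SE 0.17) and PGAM1 (1.31, SE 0.18) rose.

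Cytosolic ribosomal protein genes were higher in 8 of 47 and lower in 1 (22 and 1 after scaling, 10 and 7 after quantile normalization; 4 and 1 adjusted over the list alone). RPL24 (0.92, SE 0.14) and RPSA (1.23, SE 0.22) rose and RPS19 fell (-1.84, SE 0.31); genes of this family have many processed pseudogenes. The list was called higher (camera adjusted p = 0.00139), but not with an estimated correlation (adjusted p = 0.898), and adjusted p was 0.0794 without mimic sample 1, 0.916 after quantile normalization and 0.509 by fry (range 1.18e-05 to 0.916). Nuclear-encoded respiratory chain genes were higher in 6 of 36 and lower in 3 (16 and 1 after scaling; 6 and 2 adjusted over the list alone). ATP synthase genes ATP5PB (1.37, SE 0.23) and ATP5MC1 (1.07, SE 0.20) rose and the complex I gene NDUFV2 fell (-0.91, SE 0.16). This call (camera adjusted p = 0.00695) was also lost with an estimated correlation (adjusted p = 0.898), without mimic sample 1 (0.0951) and after quantile normalization (0.616). At a mean of at least 5 FPKM (0.107), among protein-coding genes (0.0509) and by fry (0.66) it did not pass either (range 0.00018 to 0.898). Of 15 mitochondrially encoded genes 2 were higher and 1 was lower (3 and 0 after scaling; 2 and 1 adjusted over the list alone). The higher ones were MT-ND6 and MT-ATP8, and the lower was the ribosomal RNA gene MT-RNR1 (-0.79, SE 0.21; adjusted p = 0.0136, and 0.121 after median-of-ratios scaling). The list passed (camera adjusted p = 0.0459) on the deposited scale but not with an estimated correlation (adjusted p = 0.898), after median-of-ratios scaling (0.259) or after quantile normalization (0.945). It was also lost after GC and length correction (0.11), with mitochondrial genes left out of the total (0.0739), at a mean of at least 5 FPKM (0.169) and by fry (0.652). Leaving out control sample 1 (0.139), control sample 2 (0.118) or mimic sample 3 (0.355) ended it too (range 0.00103 to 0.945). It was kept with the replicate number as a block (camera adjusted p = 0.00335).

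Mitosis genes were higher in 11 of 38 and lower in 6 (17 and 3 after scaling; 11 and 6 adjusted over the list alone). PLK1, a kinase of mitotic entry, rose from 28.1 ± 1.09 to 83.4 ± 4.33 FPKM (1.55, SE 0.12, adjusted p = 5.86e-05), BIRC5, which encodes survivin, from 7.52 ± 0.819 to 17.2 ± 1.46 (1.14, SE 0.14), and the kinesin gene KIF23 fell from 60.8 ± 0.871 to 26.5 ± 2.15 (-1.19, SE 0.12). The list was called higher (camera adjusted p = 0.0326), but not with an estimated correlation (adjusted p = 0.898), after quantile normalization (0.744), or without control sample 1 (0.0558) or mimic sample 2 (0.0589). The call also ended at a mean of at least 5 FPKM (0.169), among protein-coding genes (0.152) and by fry (0.333; range 0.0019 to 0.898). Cell cycle G1/S and replication genes were higher in 3 of 39 and lower in 13 (12 and 4 after scaling; adjusted p = 0.625). The ribonucleotide reductase gene RRM1 rose (1.03, SE 0.14), and E2F7 (-1.12, SE 0.14) and the polymerase gene POLE (-0.90, SE 0.13) fell.

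Of the lists of platinum transport, DNA repair, apoptosis and p53 targets, none was called by camera. By fry, which does not compare a list with other genes, 2 were called lower, nucleotide excision and crosslink repair (adjusted p = 0.0157) and p53 targets (0.0372). Platinum transport and detoxification genes were higher in 8 of 30 and lower in 10 (12 and 6 after scaling; adjusted p = 0.243). The metallothionein gene MT2A, a metal-binding thiol protein, fell from 360.1 ± 4.97 to 139.9 ± 10.6 FPKM (-1.36, SE 0.13, adjusted p = 0.00014), ABCC3 fell as above, and the glutathione transferase gene GSTM3 rose from 17.5 ± 1.44 to 42.6 ± 4.47 (1.26, SE 0.14). Nucleotide excision and crosslink repair genes were lower in 19 of 38 and higher in 3 (12 and 6 after scaling; adjusted p = 0.336). The translesion polymerase gene REV1 (-1.48, SE 0.17) and the Fanconi genes FANCD2 (-1.13, SE 0.15) and FANCL (-1.06, SE 0.13) fell. Mismatch and base excision repair genes were lower in 8 of 25 and higher in 3 (4 and 8 after scaling; adjusted p = 0.555). The glycosylase gene NEIL1 (-1.35, SE 0.12) and the mismatch repair gene PMS1 (-0.77, SE 0.15) fell, as did MBD4 (-0.61, SE 0.12; adjusted p = 0.00314, and 0.0527 after median-of-ratios scaling). BCL2 family and apoptosis genes were lower in 10 of 37 and higher in 6 (9 and 9 after scaling; adjusted p = 0.487). BIRC3, an inhibitor of apoptosis (-1.78, SE 0.18), and the pro-apoptotic BMF (-1.75, SE 0.18) fell. Of 28 p53 targets 11 were lower and 1 was higher (8 and 5 after scaling; adjusted p = 0.625), among them the kinase genes PLK3 (-1.36) and PLK2 (-1.20) and the growth arrest gene GADD45A (-1.07).

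**Figure D4:**
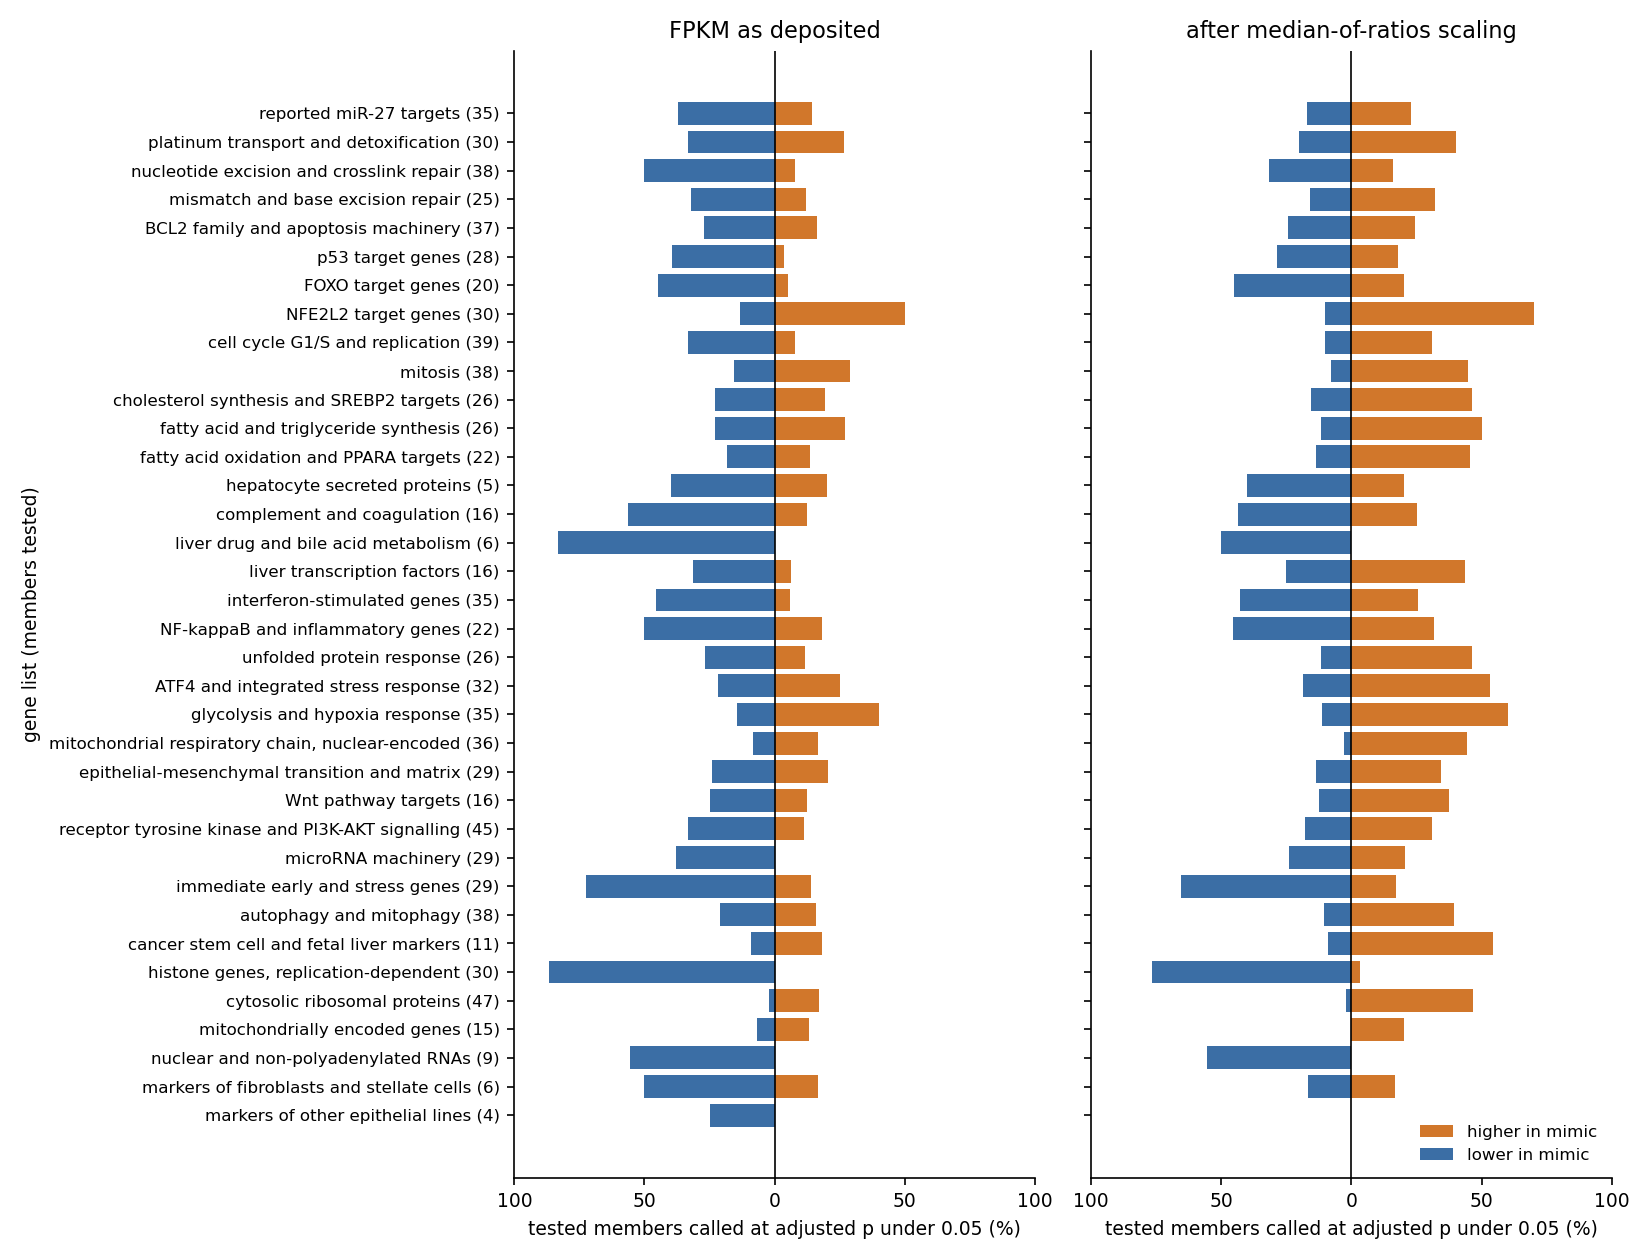
For 36 gene lists, bars give the percentage of tested members called higher (orange, right) or lower (blue, left) in mimic samples on the deposited FPKM scale and after median-of-ratios scaling, with the number of tested members in brackets. Histone and immediate early genes lie mostly on the lower side on both scales (26 of 30 and 21 of 29 on the deposited scale), whereas lists such as mismatch and base excision repair change sides.

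In lipid metabolism, cholesterol synthesis genes were higher in 5 of 26 and lower in 6 (12 and 4 after scaling; adjusted p = 0.343), and HMGCS1 (-2.00, SE 0.19) and IDI1 (-1.14, SE 0.14), both enzymes of the mevalonate pathway, fell. Fatty acid and triglyceride synthesis genes were higher in 7 of 26 and lower in 6 (13 and 3 after scaling; adjusted p = 0.125, and 0.0185 with no filter on low values). The transcription factor gene MLXIPL (-1.39, SE 0.13) and the acetyl-CoA synthetase gene ACSS2 (-1.19, SE 0.15) fell, and the lipid droplet gene PLIN3 rose (1.02, SE 0.15). Fatty acid oxidation genes were higher in 3 of 22 and lower in 4 (10 and 3 after scaling; adjusted p = 0.188), with PDK4 and the coactivator gene PPARGC1A (-1.21, SE 0.16) lower and ECI2 (0.92, SE 0.18) higher. FOXO targets were lower in 9 of 20 and higher in 1 (9 and 4 after scaling; adjusted p = 0.343), among them PDK4, the pseudokinase gene TRIB1 (-2.26, SE 0.13) and RICTOR (-1.58, SE 0.18).

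In the signalling list of receptor tyrosine kinases and PI3K-AKT, 15 of 45 genes were lower and 5 higher (8 and 14 after scaling; adjusted p = 0.752). The ERK phosphatase genes DUSP5 (-3.34, SE 0.17), DUSP6 (-2.83, SE 0.14) and DUSP4 (-2.13, SE 0.13) fell. Epithelial-mesenchymal transition and matrix genes were lower in 7 of 29 and higher in 6 (4 and 10 after scaling; adjusted p = 0.466). Of these the matricellular genes CCN2, CCN1 (-3.66, SE 0.13, from 856.8 ± 42.4 to 67.4 ± 2.37 FPKM) and THBS1 (-2.98, SE 0.16) fell. Wnt targets were lower in 4 of 16 and higher in 2 (2 and 6 after scaling; adjusted p = 0.409), with the transcription factor gene TBX3 (-1.79) lower and GLUL, glutamine synthetase (1.39), and the coreceptor gene LRP5 (0.79) higher. Autophagy and mitophagy genes were lower in 8 of 38 and higher in 6 (4 and 15 after scaling; adjusted p = 0.138, and 0.0383 with no filter on low values). The mitochondrial kinase gene PINK1 (1.47, SE 0.19) and the lysosomal gene LAMP1 (1.03, SE 0.14) rose, and ATG12 fell (-0.97, SE 0.13).

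Most genes of hepatocyte secreted proteins were near 0 in both groups. Of 30 secreted protein genes 24 were under 1 FPKM in all 6 samples, among them ALB, which encodes albumin (listed at no more than 0.011), AFP, which encodes alpha-fetoprotein (at no more than 0.024), and the apolipoprotein gene APOB (0 in all), chosen after their values were seen. Of the 5 tested, 2 were lower and 1 was higher (2 and 1 after scaling; adjusted p = 0.701): SERPINF1 (-1.91, SE 0.16) and ITIH4 (-0.93, SE 0.16; adjusted p = 0.00202, and 0.402 after quantile normalization) fell, and VTN, which encodes vitronectin, rose (0.78, SE 0.24). VTN lost its call without mimic sample 1 (adjusted p = 0.0704) and without mimic sample 2 (0.0599). Complement and coagulation genes were lower in 9 of 16 and higher in 2 (7 and 4 after scaling; adjusted p = 0.409), with CFI (-1.69) lower and C4BPA (1.78) higher. Of 37 liver drug and bile acid genes 31 had a mean under 1 FPKM. Among those were the bile acid genes CYP7A1, CYP8B1 and ABCB11, chosen after their values were seen. Of the 6 tested, 5 were lower and none higher (3 and 0 after scaling, camera adjusted p = 0.0716). Camera called the list lower after GC and length correction (adjusted p = 0.0425), with the block as well (0.0411) and among protein-coding genes (0.0351). With an estimated correlation it did not (0.898). Tested by fry, without comparison to other genes, the list was lower (adjusted p = 0.000252). The dioxin-inducible CYP1A1 fell from 47.2 ± 1.72 to 5.72 ± 0.453 FPKM (-2.94, SE 0.12). Liver transcription factors were lower in 5 of 16 and higher in 1 (4 and 7 after scaling; adjusted p = 0.724), including ONECUT2 (-1.56) and CEBPG (-0.78).

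Markers of stem cells and fetal liver were higher in 2 of 11 and lower in 1 (6 and 1 after scaling; adjusted p = 0.161). KRT19, a keratin of bile duct cells, rose (1.28, SE 0.20), KLF4 fell (-1.65, SE 0.29), and IGF2BP2 passed narrowly (0.59, SE 0.22, adjusted p = 0.0487), losing its call without any of control samples 1, 2 and 3 and mimic samples 2 and 3 (adjusted p up to 0.288 over the alternatives). Fibroblast and stellate cell markers were lower in 3 of 6 and higher in 1 (1 and 1 after scaling; adjusted p = 0.936). COL1A1, a collagen gene, fell (-1.09, SE 0.15), and TAGLN rose (0.58, SE 0.16, adjusted p = 0.0152, and 0.0595 without control sample 2), while ACTA2 fell on the deposited scale (-0.62, SE 0.17, adjusted p = 0.0159) but did not pass after median-of-ratios scaling (0.0815) or without control sample 2 (0.0612). Of 4 tested markers of other epithelial lines 1 was lower (0 after scaling; adjusted p = 0.936), PAX8 (-0.78, SE 0.19, adjusted p = 0.0106, and 0.0805 after median-of-ratios scaling), and KRT17 was at 453.3 ± 41.9 and 333.9 ± 93.1 FPKM (adjusted p = 0.0935). KRT17 was called lower with the block (adjusted p = 0.0331), after quantile normalization (0.0177), after GC and length correction (0.0406) and with both block and correction (0.0248). It was also called with mitochondrial genes left out of the total (0.0381) and without mimic sample 1 (0.00539), but not after median-of-ratios scaling (0.509). Only 2 endothelial and 2 leukocyte markers had a mean of 1 FPKM, too few for a set test. EGFL7 (-0.83, SE 0.19) and S100A9 (-1.70, SE 0.21) fell, CD68 rose (0.91, SE 0.22), and ESAM had a log2 fold change of -0.59 (adjusted p = 0.198, and 0.00155 without mimic sample 1).

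Across the 36 lists the counts adjusted over the list alone equalled those over all genes in 25. Besides the lists above, they gave 3 higher and 11 lower for G1/S genes, 2 and 4 for fatty acid oxidation, 2 and 10 for complement and coagulation, 0 and 5 for liver transcription factors, 4 and 14 for receptor signalling, 0 and 10 for the microRNA machinery, 5 and 7 for autophagy, 1 and 1 for stem cell markers and 0 and 6 for nuclear RNAs. Camera compares a list with all other genes, so its direction was up although the median lay below 0 for platinum transport, mismatch repair, BCL2 family, G1/S, cholesterol synthesis, liver transcription factor, matrix, Wnt, receptor signalling and epithelial marker genes. The median lay above 0 and the mean below it for fatty acid synthesis, fatty acid oxidation, unfolded protein response and ATF4 genes.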

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

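The scaling without mitochondrial genes, the GC and length correction without a block, the fit on protein-coding genes and the fit without sample 3 of both groups were chosen after the results were seen; the other alternatives were planned. The planned Wald and voom tests need counts and were not run.

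Among 116 named genes that passed, 2035 of 2069 values under 18 alternatives kept direction and call. The call was lost in 34, the direction changed in 0, and 12 genes lost the call at least once. Most of these genes were picked for large changes or small p, so they do not stand for all calls. Of all 7453 called genes, 4905 kept call and direction after quantile normalization, 5687 after median-of-ratios scaling and 5460 after GC and length correction. The number of higher genes moved from 1735 to 3592 after quantile normalization, 3889 after median-of-ratios scaling, 3157 after GC and length correction and 3255 with the block and that correction. At least 2-fold higher genes moved from 356 to 915, 968, 633 and 646 in that order. Lower genes moved from 5718 to 3289 after quantile normalization, and at least 2-fold lower ones from 2666 to 1151, with 1637 after median-of-ratios scaling, 1444 after GC and length correction and 1446 with the block as well. The cause was not tested beyond the shift of all genes. With other sets of genes tested, lower genes numbered 8755 with no filter, 2916 at a mean of at least 5 FPKM and 3737 among protein-coding genes, and at least 2-fold lower ones 1159 and 1384 for the last pair. Leaving out each sample gave 1256 to 1822 higher and 4695 to 5732 lower genes.

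The replicate number as a block gave 2117 higher and 5994 lower genes, 362 and 2673 of them at least 2-fold, and 9 called lists. It gained the ATF4 list (adjusted p = 0.0373) and KRT17 (0.0331). It ended the call of IGF2BP2 and ENSG00000268173, and of the 8mer genes (adjusted p = 0.0564). Deviations of samples with the same number correlated across genes at 0.177, -0.047 and 0.223. Control samples 1 and 3 correlated best with the mimic sample of their own number, and control sample 2 with mimic sample 1 (0.126). The second principal component, with 10.3% of the variance, fell with the sample number in both groups. It was at 12.15, 8.16 and -20.76 in control samples 1, 2 and 3, and at 30.56, -5.85 and -24.25 in mimic samples. With 3 samples per group, these values cannot tell whether the numbers pair the samples.

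Of 8 gene lists called, 0 were called with camera at an estimated correlation, where no list had an adjusted p under 0.898. That held even for immediate early genes, whose estimate of 0.013 was near the preset 0.01. Losing a call there therefore does not tell the lists apart. Fry, which asks another question, called 17, of which 15, all lower, were not called by camera. Leaving out each sample gave 6 to 8 lists called by camera. The difference of genes with any seed match moved from -0.1372 to -0.0333 after quantile normalization, -0.0345 after GC and length correction and -0.0809 with no filter. It was -0.1402 at a mean of at least 5 FPKM and ranged from -0.1715 to -0.0957 over samples left out, where the former and that without mimic sample 2 passed 0.05 before adjustment over classes. The seed word's rank moved from 1686 to 1144 with the UTR of the longest coding sequence, 3653 without covariates, 4927 after quantile normalization, 2757 with no filter and 1260 at a mean of at least 5 FPKM, with 1393 to 2198 over samples left out; the cause was not tested. CD68 lost its call without sample 3 of both groups (adjusted p = 0.0853), PMS1 after quantile normalization (0.0918) and NDUFV2 after GC and length correction (0.0524).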

Other observations

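The tests of RNA handling, of failed estimates, of other cells, of GC content behind the seed difference and of other splits were chosen after the results were seen, as was the estimate of fragment numbers.

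Besides the classes described above, 143 of 201 transcribed unprocessed pseudogenes were lower and 5 higher in mimic samples (median log2 fold change -0.94), and 84 of 111 sense intronic transcripts were lower and 2 higher (median -1.12). After GC and length correction 45 sense intronic transcripts were lower and 9 higher (median -0.42), and the median of the pseudogenes was -0.64. Processed pseudogenes were lower in 175 of 364 and higher in 40 (median -0.54), in 131 and 73 after median-of-ratios scaling, and in 86 and 111 after GC and length correction (median 0.09). Mitochondrial tRNA genes were divided, with 6 of 22 higher and 5 lower (median 0.03), but 14 higher and 1 lower after GC and length correction (median 1.40). These classes overlap or resemble other genes, so their single values are uncertain. B2M, which encodes the light chain of class I antigen presentation and was chosen after its values were seen, differed by -2.45 on the log2 scale (adjusted p = 0.0118 by limma). On the deposited scale words rich in A and T in the 3' UTR went with lower values: besides the lowest words above, TTTATAT (z = -5.53) and TAATTTA (-5.43) were among the lowest.

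Genes of non-coding and other biotypes fell more than protein-coding genes, with medians of -0.93 and -0.17. The gap was -0.513 after GC and length correction, beyond the bound of -0.25 set for that explanation, so this bias does not account for the whole gap. Among genes with a mean of at least 5 FPKM it was -0.779, which argues against lower depth of the mimic libraries. The implied fragment numbers, larger in mimic samples, point the same way, but reads per gene were not recovered to check them. The mean log2 fold change of MALAT1 and NEAT1 minus the protein-coding median was -2.109. That may come from RNA or library handling that differed between the groups as well as from the mimic itself, which the design gives as the biological explanation, and these cannot be told apart, since the labels record no handling or library batch per sample. The same doubt holds for the short-lived immediate early mRNAs (21 of 29 lower) and for the histone mRNAs without a poly(A) tail (26 of 30 lower), which fell together with them, and whether libraries were made from poly(A) RNA is not given.

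Most genes of hepatocyte secreted proteins were near 0, although the label gives a hepatocellular carcinoma line; VTN averaged 77.0 FPKM. Chosen after their values were seen, CP averaged 6.71 and the complement genes C4BPB and C3 averaged 170.8 and 132.9 FPKM. Failed estimates would also lower abundant genes, but 0.0% of 83 ribosomal and respiratory chain genes had a mean under 1 FPKM. With 24 of 30 hepatocyte genes under 1 FPKM in all 6 samples, cells other than the labelled line remain possible. Of the markers of other epithelial lines 14 of 18, and of fibroblasts 11 of 18, were also under 1 FPKM in all 6 samples, with KRT17 (393.6 FPKM) and FBLN1 (309.7, chosen after its values were seen) the most abundant of each list. A line that lost hepatocyte expression could give the same values, and these cannot be told apart since no sample of known identity was analysed here.

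Genes with an 8mer seed match were lower than genes without one, by 0.18 at the median. The difference was -0.0775 after GC and length correction, a loss of more than the bound set for that explanation, so GC content and length may account for much of it. Among 630 words of the same base composition the seed word lay at percentile 8.25, between the bounds of 5 and 25 set beforehand, so whether the match itself matters cannot be told apart from its composition. The percentile was 34.0 after quantile normalization, beyond the upper bound, and 5.24 with the UTR of the longest coding sequence. Direct repression by the mimic stays open as the biological explanation.

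Among the 10 splits of the 6 samples into 3 and 3, the real one called 7453 genes and the highest of the others 0 by limma, with up to 578 genes at an unadjusted p under 0.05 against 8294. Only the real split reached its number, but 10 splits are too few for a share under 0.05. Each other split mixed the groups on both sides, which puts the difference between groups into the spread. Their 0 calls therefore do not measure what chance would give.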
